A study of Mus musculus with 6 samples.

How the data were processed

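Gene expression was measured in KPC001, a pancreatic cancer cell line derived from a KPC mouse, a genetically engineered model of pancreatic cancer. The line was cultured in high-glucose medium with serum, and cells were separated by CD133, a surface glycoprotein encoded by Prom1 that is used as a marker of tumour-initiating cells. Total RNA from 3 CD133-positive and 3 CD133-negative samples was purified with Trizol and a column, treated with DNase I, and amplified into biotin-labelled cRNA with the Ambion MessageAmp kit, per the labels' protocols. Each sample was hybridised to 1 Illumina mouse whole-genome bead array in 1 colour. Each sample's group came from its label for the cell population and its replicate number from its title, where the sample without a number was taken as replicate 1. The labels do not state whether the replicates came from separate cultures or sorts, so the p-values measure only the spread between these samples, which may be technical. Slide and scan date were not given in the sources used here.

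Per the file headers, the deposited table held for each of 45281 probes and each array a mean bead intensity on a linear scale, a standard error of the bead intensities, a number of beads and a detection p-value. The deposited detection p-values lay on even steps that correspond to a rank among 936 negative control probes, and the deposited intensities were neither background-subtracted nor normalized. A second deposited table held intensities processed by the authors. Set against the same array's deposited intensity, each of its columns had a rank correlation of 1, a ratio between 0.852 and 1.105 and a median between 118.7 and 120.5. These authors' intensities were therefore on a linear scale without centring of genes, and the method that made them is not given in the sources used here.

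Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, with the mean and spread of the negative controls inferred from the detection p-values and an offset of 16, followed by log2 transformation and quantile normalization (neqc). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which left 17219 probes. Gene symbols came from the platform annotation, which can be old. Of the 45281 probes, 34885 had 1 symbol, 18 had several and 10378 were not listed and are unnamed here. The symbols of 34807 probes were found again through their gene identifier in a RefSeq gene table, and 0 of them changed. The tested probes with 1 symbol numbered 14752 and stood for 9430 genes.

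The groups were compared with limma (lmFit and eBayes, two-sided, no covariates), and a probe passed the threshold at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. Differences are log2 intensity in CD133-positive minus CD133-negative cells, given ± the standard error of the fit with n = 3 per group, or as group means ± SD. Intensities of dim probes are compressed by the offset, which makes their log2 differences smaller. Where a probe was not above background on any array of a group, the fold is given as a lower bound, from the bright group's mean against the mean of, per array, the higher of the lowest signal among detected probes and the dim probe's own signal. Probes of a gene were tested separately, and their mean intensities served to rank them by brightness and to group genes by the gap between the brightest and the dimmest probe.

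The genes to be named were fixed by a rule. They were Prom1, then the 8 genes with the largest rise and the 8 with the largest fall among probes that passed and whose groups did not overlap, with 1 probe per gene (the smallest p) and without unnamed probes or probes of several genes. From each gene list the rule took up to 4 members that passed, or, where none passed, the 2 members with the smallest p, given as values. Named genes with tested probes of opposite sign at an unadjusted p under 0.05 were to be given with both values.

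A total of 24 gene lists were fixed. They covered stem and tumour-initiating cell surface markers, self-renewal transcription and chromatin factors, the Notch, Wnt and Hedgehog pathways, epithelial and ductal markers, mesenchymal markers, TGF-beta targets, cell division, NF-kappaB targets and inflammatory cytokines, survival and apoptosis regulators, heat shock proteins, the unfolded protein response, the interferon response, hypoxia and glycolysis, cholesterol synthesis, ABC transporters, immediate early genes, oxidative stress and NRF2 targets, ribosomal proteins, and leukocyte, endothelial, fibroblast and stellate, and acinar and endocrine markers as signs of other cell types. Each gene was represented by its tested probe with the highest mean log2 intensity. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, adjusted over these lists, beside camera with an estimated correlation, its rank form, and the rotation test fry. The comparisons, lists, naming rule and all the alternatives below but the brightest probe of each gene were written before the data were examined, and the tests on other probes of genes that passed were written after.

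The tests were checked on simulated data built from the spread of the real arrays, with independent noise for each probe. With 200 of 17219 probes changed, log2 differences of 0.5 were recovered for 0% of them, differences of 1 for 95% and differences of 2 for 100%. The share of false calls was 5.47% at a difference of 1 and 8.26% at a difference of 2. In the real data probes passed from a difference of 0.42 upward, so these shares do not carry over to them directly. In 20 simulated draws with 1 of 21 lists shifted by 0.3, the shifted list was recovered in 20 draws with 0 false calls. The real medians of the tested lists were smaller, from -0.16 to 0.14, and real genes can be correlated. These draws therefore do not show the power of the list test in the real data.

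Alternatives were normal-exponential correction without negative controls (offset 50), no background correction (values under 1 raised to 1), a median shift or cyclic loess in place of quantile normalization, the authors' intensities on a log2 scale, no filter on dim probes, a detection p under 0.01 on all 6 arrays, the replicate number as a block, a variance trend with robust estimation, array quality weights, each array left out in turn, probes of a gene averaged, and the brightest probe of each gene. Figures were drawn with matplotlib 3.10.9. RefSeq positions served only to order genes along chromosomes and to give gene lengths.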

Results

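The data comprised 6 arrays of the mouse pancreatic cancer cell line KPC001, 3 from CD133-positive and 3 from CD133-negative cells. Between 17123 and 18057 of the 45281 probes on an array, 37.8% to 39.9%, were detected at a detection p under 0.05. The median number of beads behind a probe was 37 to 41 per array, and the median signal of detected probes was 1.92 to 2.20 times the background level. Arrays of the same group differed by 1.34 to 1.51 times the error expected from their beads, and arrays of different groups by 1.71 to 1.84 times, so no array duplicated another. The first principal component held 35.2% of the variance and separated the CD133-positive arrays (scores 13.9 to 16.2) from the CD133-negative arrays (scores -15.6 to -14.2). The number of arrays limits the precision, with a median standard error of 0.11 for a log2 difference.

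The comparison asked which genes differ in expression between the CD133-positive and the CD133-negative population of this line. Prom1, which encodes CD133 itself, was not detected by any of its 3 probes on any of the 6 arrays. Its mean log2 intensities lay at background in both populations, at 4.47 ± 0.11 (SD, n = 3) against 4.40 ± 0.09 for ILMN_1238150, 4.37 ± 0.09 against 4.39 ± 0.11 for ILMN_1249786 and 4.46 ± 0.13 against 4.53 ± 0.10 for ILMN_2505476. No fold is given for Prom1, and its transcript does not check the labels of these arrays.

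Npm3-ps1, an annotated pseudogene of the nucleoplasmin family gene Npm3, had the largest rise of any named gene in CD133-positive cells, 2.46 ± 0.13 on the log2 scale (5.49-fold, adjusted p = 0.000451, n = 3 per group). Probe sequences were not used here, so this signal cannot be assigned to the pseudogene rather than to Npm3. Fam135a had the largest fall, from a mean log2 intensity of 8.44 ± 0.11 (SD) in CD133-negative to 6.10 ± 0.07 in CD133-positive cells, a difference of -2.34 ± 0.09 (adjusted p = 0.000107), which was -1.41 with the authors' intensities. In all, 264 of 17219 tested probes passed the threshold, 216 higher and 48 lower in CD133-positive cells. At an unadjusted p under 0.05 the numbers were nearer to each other, with 1564 higher and 1295 lower. At that level 825 of 3286 were higher with a median shift, which left the median of all tested probes at -0.13. The 264 probes stood for 155 genes higher and 42 genes lower, and 55 of these probes had no gene name. Of all tested probes 23.1% had groups that did not overlap, where chance gives 10% for 3 against 3. Changes were moderate, with 18 probes changed at least 2-fold and 182 at least 1.5-fold.

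**Figure D1:**
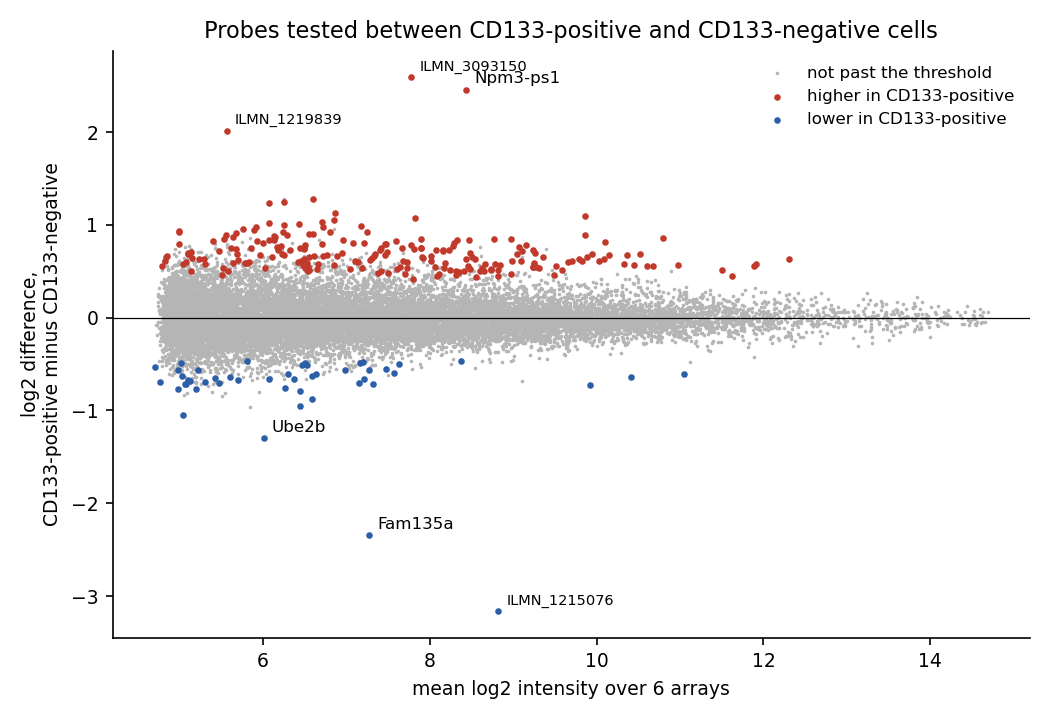
Log2 difference between CD133-positive and CD133-negative cells against mean log2 intensity for each of the 17219 tested probes, with 3 arrays per group. The 216 probes higher in CD133-positive cells (red) outnumber the 48 lower ones (blue), and Fam135a, Npm3-ps1 and 3 unnamed probes lie farthest from 0.

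Among the genes with the largest rises, Hebp1, a heme-binding protein, rose by 1.25 ± 0.10 on its single tested probe, a 2.38-fold rise (0.55 without background correction and 0.56 with the authors' intensities). Ncoa4, a nuclear receptor coactivator that also delivers ferritin to autophagy, rose by 1.13 ± 0.09. Its other tested probes gave 0.58 ± 0.11 and 0.00 ± 0.10. Mcu, the pore of the mitochondrial calcium uniporter, rose by 1.03 ± 0.15 and by 0.75 ± 0.13 on both of its tested probes. Prrc2c rose by 1.06 ± 0.10 on one probe and 1.01 ± 0.12 on another, while its remaining tested probes lay between 0.36 and 0.53. Npm3-ps1 also rose on its second probe, by 0.58 ± 0.08. Ptprs, a receptor-type tyrosine phosphatase, rose by 1.24 ± 0.10 on ILMN_1241523, beside 0.01 ± 0.10 and -0.02 ± 0.11 on the other tested probes. Zdhhc13, a palmitoyltransferase, rose by 1.02 ± 0.12, beside 0.01 ± 0.10 and -0.11 ± 0.08. Yme1l1, a protease of the mitochondrial inner membrane, rose by 1.08 ± 0.10, beside -0.11 ± 0.11 and 0.51 ± 0.14. Without background correction Ptprs had 0.51 and Zdhhc13 0.41. Over other settings on the same probes, the replicate block aside, the smallest rises were 0.53 for Mcu, 0.61 for Ncoa4 and 0.57 for Prrc2c. They were 0.75 for Yme1l1 and 1.89 for Npm3-ps1. Ptprs, Ncoa4 and Npm3-ps1 passed in all of these settings and the other genes of this paragraph did not.

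Most of the largest falls were also seen with a single probe of the gene. Ube2b, a ubiquitin-conjugating enzyme of DNA repair, fell by 1.30 on the log2 scale (SE 0.08, adjusted p = 0.00162) on ILMN_2497877, while its other tested probe gave 0.20 ± 0.09. Without background correction Ube2b had -0.52. The other tested probe of Fam135a gave -0.08 ± 0.09. Sema3c, a secreted semaphorin, had -0.95 ± 0.14 on the probe that passed and -0.05 ± 0.10 on the other. For Qrich1 the values were -0.88 ± 0.08 on the probe that passed and -0.02 ± 0.08 and 0.04 ± 0.14 on the others. Tagap, a GTPase-activating protein, had -0.77 ± 0.13 and -0.16 ± 0.11. Pank3, a pantothenate kinase of coenzyme A synthesis, fell on its single tested probe, with -0.79 ± 0.13. Over other settings on the same probes, the replicate block aside, the smallest falls were -0.43 for Sema3c, -0.42 for Qrich1, -0.23 for Tagap and -0.36 for Pank3. Each of these genes missed the threshold in at least 1 of those settings. The probes of Armc9 and Dlgap4 that passed (ILMN_2551962 and ILMN_1232585) were not above background on any CD133-positive array and were at least 1.58-fold and at least 1.37-fold lower there with background correction, and had -0.34 and -0.23 without it. Both genes were detected on all 6 arrays by another probe. The other tested probes of Dlgap4 gave -0.24 ± 0.11 and -0.41 ± 0.09, and those of Armc9 lay between -0.24 and -0.05.

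**Figure D2:**
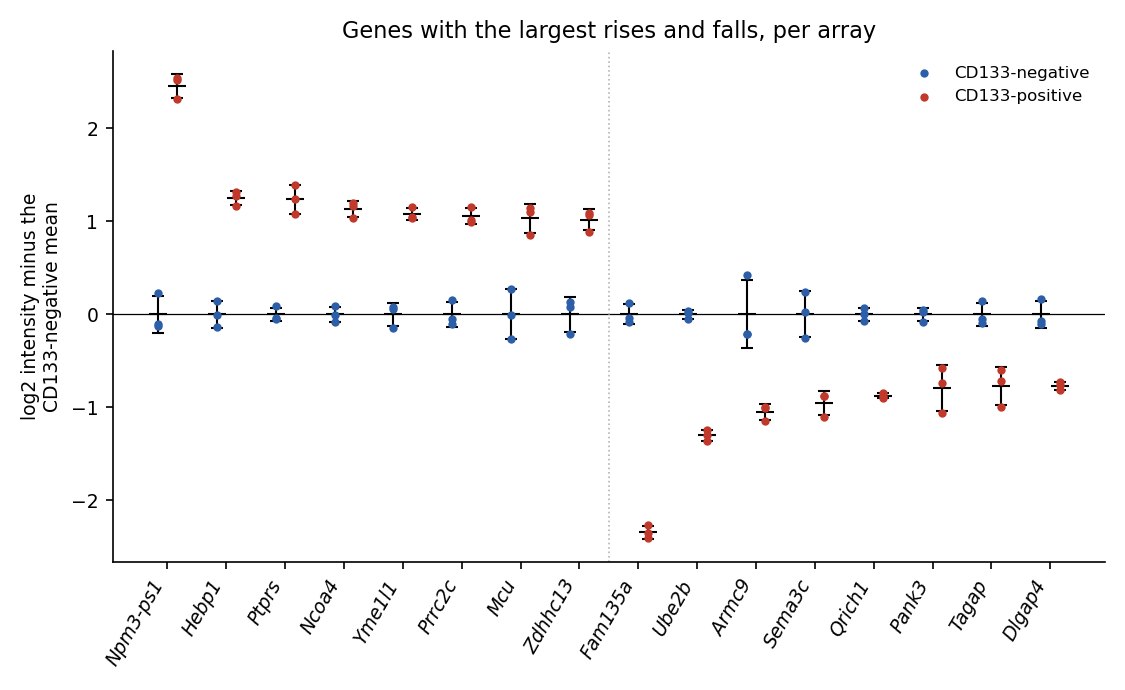
Log2 intensity of the 8 genes with the largest rises and the 8 with the largest falls on each of the 6 arrays, minus the gene's CD133-negative mean. Points are arrays, horizontal marks are group means and bars are SDs (n = 3), and the differences run from 2.46 for Npm3-ps1 to -2.34 for Fam135a.

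Probes of the same gene often differed across all genes that passed. Of the 155 genes with a higher probe, 109 had another tested probe, and the median log2 difference was 0.68 for the probe that passed against 0.03 (95% bootstrap interval -0.0034 to 0.060) for the brightest other probe. That other probe had the same sign at an unadjusted p under 0.05 in 26 genes, the opposite sign in 5 and did not reach that level in 78. Of all 17219 tested probes 1564 were higher and 1295 lower at that level. The 26 were thus a larger share than among all tested probes, and the 5 a smaller one. The 5 genes with the opposite sign, chosen after their values were seen, were Asph, Hnrnpk, Itgb1, Lpp and Ptpn12. Of the 42 genes with a lower probe, 23 had another tested probe, and the medians were -0.65 and -0.09.

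**Figure D3:**
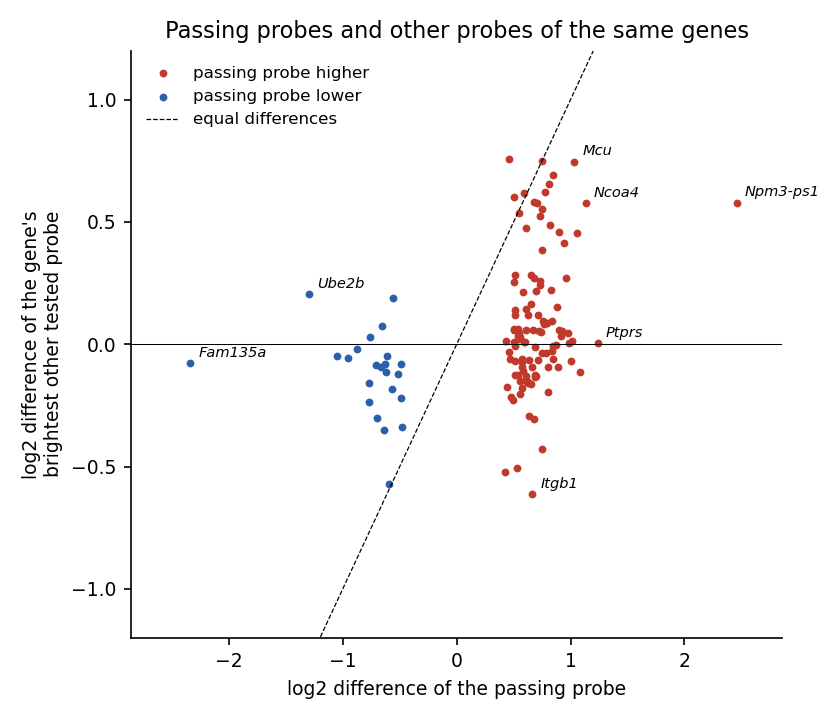
Log2 difference of the probe that passed (horizontal axis) and of the brightest other tested probe of the same gene (vertical axis), for 109 genes with a higher probe (red) and 23 with a lower probe (blue). The dashed line marks equal differences, and most genes lie near 0 on the vertical axis, with medians of 0.03 and -0.09.

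The number of probes that passed depended on the full set of arrays. It was 10, 14 and 13 without CD133-negative replicate 1, 2 and 3, and 7, 11 and 8 without CD133-positive replicate 1, 2 and 3, and 7 of the 264 probes passed in each of these fits. The 7 included Fam135a, Npm3-ps1, Ube2b, Ptprs and Ncoa4, and all 264 kept their direction in each.

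Within the fixed gene lists, 5 of 332 tested member genes passed over all tested probes. Of all tested probes 264 of 17219 passed, a share close to that of the list members. Nsdhl, a sterol dehydrogenase of cholesterol synthesis, rose by 0.88 ± 0.10 in CD133-positive cells (adjusted p = 0.0169). Thbs1, the matrix protein thrombospondin 1, rose by 0.84 ± 0.12 (adjusted p = 0.0280). Pfkp, the platelet form of phosphofructokinase, rose by 0.51 ± 0.08 (adjusted p = 0.0399), and Dclk1, a kinase that marks tuft cells, rose by 0.51 ± 0.09 (adjusted p = 0.0445). Abce1 fell, with -0.50 ± 0.08 (adjusted p = 0.0379). It belongs to the ABC family by sequence but recycles ribosomes and is not a membrane transporter. Over other settings on the same probes, the replicate block aside, the smallest differences were 0.37 for Nsdhl, 0.35 for Thbs1 and 0.35 for Pfkp. They were 0.14 for Dclk1 and -0.33 for Abce1. The highest adjusted p of each of these 5 genes there lay between 0.078 and 0.229. No list passed as a whole among the 21 with at least 5 tested genes. By camera 0 lists passed (smallest adjusted p = 0.163) and 2 did at an unadjusted p under 0.05, and with an estimated correlation the smallest adjusted p was 0.691. The rotation test fry called 0 lists for a shift in one direction (smallest adjusted p = 0.0516, 5 at an unadjusted p under 0.05). It called 13 for changes in either direction, which includes changes of some members against others. Fry does not compare a list with the other probes, and 16.6% of all tested probes had an unadjusted p under 0.05. Ribosomal proteins were among the 13 (fry adjusted p = 0.000799), with 0 of 18 members at that level. The 13 calls therefore do not set these lists apart from other genes. With the authors' intensities camera called 3 lists, cholesterol synthesis and ribosomal proteins higher and ABC transporters lower, and with the mean of a gene's tested probes it called 1, cholesterol synthesis, higher.

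The 2 lists at an unadjusted p under 0.05 by camera were cholesterol synthesis and ABC transporters. Of 16 tested cholesterol synthesis genes, 1 passed and 15 did not, and adjusted over the list alone Nsdhl and Cyp51 (0.46) passed. The list's median log2 difference of 0.14 lay 0.07 to 0.15 above the median of all tested probes under 5 other background and scaling settings, although it was -0.03 with a median shift alone, where that of all tested probes was -0.13. Other tested probes of Nsdhl gave values between 0.15 and 0.52. Of 15 tested ABC transporter genes, Abce1 was the 1 that passed, and Abca7 (-0.40) also passed adjusted over the list alone. Their median was -0.16, and it was below 0 in the same 5 settings.

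Among 13 tested stem and tumour-initiating cell surface markers, Dclk1 was the 1 that passed. Its probe lay near background in CD133-negative cells, with a mean log2 intensity of 4.88 and detection on 2 of 3 arrays. The difference shrank to 0.14 at the smallest over other settings on the same probe, the replicate block aside. The other probes of Dclk1 were not detected on any array. Adjusted over the list alone, 4 genes passed and they went both ways, with Dclk1 at 0.51 and Met at 0.73, and with Aldh1a1 at -0.46 and lower values also for Procr, which was not above background on any CD133-positive array. Cd44 had 0.18 and Cd24a 0.21, neither of which passed. Of the 13 self-renewal transcription and chromatin factors tested, 0 passed, with 0.32 ± 0.09 for Bmi1. Probes of Id2 had opposite signs, 0.27 ± 0.08 on ILMN_1236868 and -0.36 ± 0.15 on ILMN_2887239. In the Notch pathway 0 of 12 tested genes passed, and the ligand Jag1 had -0.39 ± 0.12 and the feedback regulator Nrarp -0.25 ± 0.09. In the Wnt pathway 0 of 12 passed, with 0.40 ± 0.12 for the receptor Fzd2 and -0.31 ± 0.13 for Sfrp2. In the Hedgehog pathway 0 of 7 passed, with -0.22 ± 0.11 for the ligand Dhh and 0.24 ± 0.12 for the coreceptor Cdon. Adjusted over each list alone, 0 genes of these 4 lists passed.

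Of the 20 tested epithelial and ductal markers and the 17 tested mesenchymal markers, 0 passed. The smallest p-values belonged to Lcn2 (0.51 ± 0.14) and Muc1 (0.31 ± 0.11) among the epithelial genes and to Prrx1 (0.43 ± 0.12) and Fn1 (0.28 ± 0.09) among the mesenchymal ones. Of 18 tested TGF-beta targets, Thbs1 was the 1 that passed, over all tested probes and adjusted over the list alone. Cell division genes gave 0 of 22, with Pcna at -0.53 ± 0.16 and Mcm3 at 0.32 ± 0.10. NF-kappaB targets and inflammatory cytokines gave 0 of 20, with Ccl20 at -0.22 ± 0.09 and Ccl7 at 0.23 ± 0.10. Survival and apoptosis regulators gave 0 of 20, with Bcl2l11 at 0.21 ± 0.08 and Fas at -0.33 ± 0.14. Adjusted over each list alone, 0 genes passed in these lists other than that of TGF-beta targets.

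Of 15 tested heat shock protein genes 0 passed on the probe used for the list, and Hspa8 and Hspd1 passed on a dimmer probe, with 0.63 ± 0.09 and 0.56 ± 0.08, beside -0.06 ± 0.09 and -0.12 ± 0.12 on the other tested probes of Hspa8 and -0.20 ± 0.10 on that of Hspd1. Hspa4 had -0.37 ± 0.12, and probes of Hspa4l had opposite signs, 0.33 ± 0.09 and -0.31 ± 0.12. In the unfolded protein response 0 of 20 genes passed, Ddit4 (0.46 ± 0.09, adjusted p = 0.0523) passed adjusted over the list alone, and Sdf2l1 had 0.29 ± 0.12. Of 21 tested hypoxia and glycolysis genes Pfkp was the 1 that passed, and P4ha1 (0.51) passed with it adjusted over the list alone. Interferon response genes gave 0 of 15, with Stat2 at 0.35 ± 0.13 and Bst2 at -0.55 ± 0.27. Immediate early genes gave 0 of 16, with Jund at -0.36 ± 0.15 and Atf3 at -0.21 ± 0.14. Oxidative stress and NRF2 target genes gave 0 of 20, with Nqo1 at 0.36 ± 0.09 and Gclc at -0.46 ± 0.15. Ribosomal protein genes gave 0 of 18, with Rps19 at 0.16 ± 0.08 (-0.04 with its probes averaged) and Rps15 at 0.14 ± 0.08 (-0.01 with a median shift). Adjusted over each list alone, 0 heat shock, interferon response, immediate early, oxidative stress and ribosomal protein genes passed. Cyp51, Abca7, Met, Procr, Aldh1a1, Cd44, Cd24a, P4ha1, Hspa8 and Hspd1 were chosen after their values were seen.

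Markers of other cell types were mostly not detected. Of the leukocyte markers 3 were tested, of the fibroblast and stellate markers 2 and of the acinar and endocrine markers 1, too few for a list test, and 6 endothelial markers were tested. None of these genes passed over all tested probes. Fcer1g and Eng, both not above background on any CD133-positive array and at least 1.08-fold and at least 1.16-fold lower there, passed adjusted over their lists alone, and Csf1r had -0.25 ± 0.11. Egfl7 had 0.09 ± 0.10 (-0.01 with a median shift), Col1a1 -0.27 ± 0.13, Acta2 -0.02 ± 0.08 (0.13 with its probes averaged) and Cela1 -0.09 ± 0.14. The signs of a list's median, mean and camera direction differed for mesenchymal markers, TGF-beta targets, cell division and endothelial markers.

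**Figure D4:**
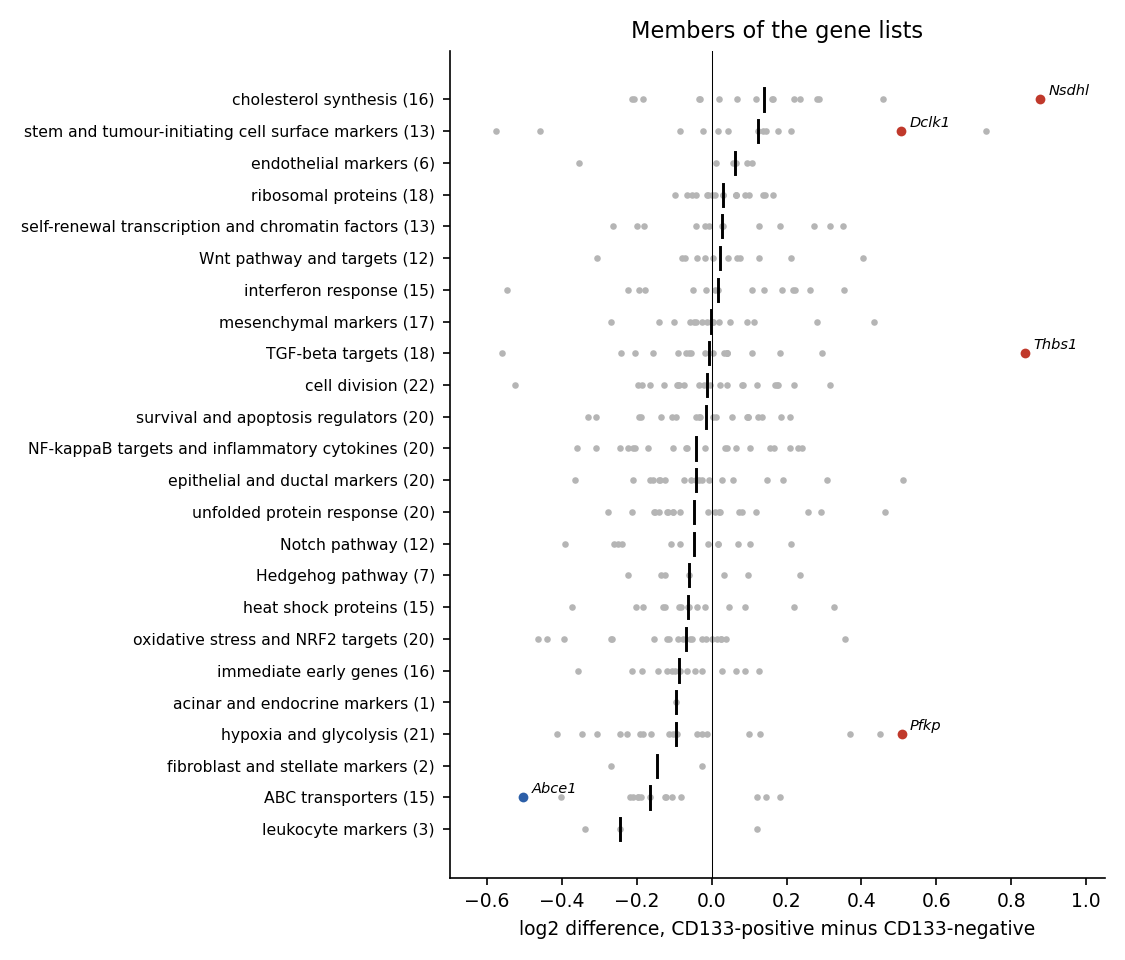
Log2 difference of each tested member of the 24 gene lists, with the number of tested genes in parentheses. Grey points did not pass, coloured points are the 5 genes that passed over all tested probes, and black bars are list medians, from -0.25 for 3 leukocyte markers to 0.14 for cholesterol synthesis.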

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

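All alternatives were planned except the brightest probe of each gene, which was chosen after the data were seen. The count of 264 probes depended strongly on the processing. It was 734 with normal-exponential correction without negative controls, 1110 without background correction, 1157 with the authors' intensities, 1095 with a variance trend and robust estimation, and 554 with detection at 0.01 on all arrays. It was 37 with a median shift, 113 without a filter on dim probes (a test over 45281 probes), 102 with probes of a gene averaged and 106 with the brightest probe of each gene (9430 genes each), and 7 to 14 with 1 array left out. Cyclic loess (301) and array weights (285) changed it little. The split of 216 higher and 48 lower became 748 and 362 without background correction. It became 25 and 12 with a median shift, where the median of all tested probes was -0.13. With probes averaged it was 77 and 25, and with the brightest probe 82 and 24. At an unadjusted p under 0.05, 1564 of 2859 probes were higher, and 825 of 3286 with a median shift, 719 of 1532 with probes averaged and 646 of 1521 with the brightest probe. Apart from the number of probes or arrays tested, the cause was not tested. With the replicate number as a block, 6 probes passed, 3 of them higher. Deviations from the group means correlated by 0.00 to 0.02 between samples of the same number and by -0.05 to 0.03 between others. Of the 6 arrays, 2 correlated best with their own number. These values gave no sign of a pairing by number, but 3 samples per group are too few to exclude a weak one.

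Prom1, at background on all arrays, was tested only without the filter on dim probes, where it did not pass. The count of 0 changed lists became 3 with the authors' intensities and 1, cholesterol synthesis, with the mean of a gene's tested probes, and stayed at 0 in the other list settings. All 264 probes kept their direction in 5 other background and scaling settings. They also kept it without each array, where it could hardly turn because their groups did not overlap. Of these probes 242 kept an unadjusted p under 0.05 without each array. Of the 21 named probes that passed, 5 passed without each array in turn. In 326 checks on the same probes their direction held in 326 and the threshold in 212. Many of these checks left out 1 array or kept the log2 intensities unchanged, and so could hardly turn a direction. Signs turned for Ube2b (0.20 on its brightest probe), for genes that had not passed with probes averaged (Id2 -0.0039, Rps19 -0.036, Acta2 0.13), with a median shift (Rps15 -0.010, Egfl7 -0.012), with the authors' intensities (Acta2 0.0038), and with 1 array left out (Acta2 from -0.051 to 0.014, above 0 without CD133-positive replicate 3, and Cela1 from -0.26 to 0.018, above 0 without CD133-positive replicate 2). A block for the slide was not run because the files give none. Detected probes had a median of 1.92 to 2.20 times background, which limits the differences that dim probes can show.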

Other observations

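The genes named here, and the tests on other probes of the same genes, were chosen after their values were seen. In all, 10 genes passed with at least 2 probes, and all of these probes were higher in CD133-positive cells. Besides Mcu, Npm3-ps1 and Prrc2c they were Acaa2, an enzyme of mitochondrial fatty acid oxidation (0.75 ± 0.09 on both probes, beside 0.54 and -0.23 on its other tested probes), Rbbp7, a histone-binding chromatin protein (3 probes, 0.58 to 0.68, beside 0.12), the tyrosine phosphatase Ptpn12 (3 probes, 0.61 to 0.80, beside 0.57 and -0.19), Pik3r1, the regulatory subunit of PI3-kinase (0.52 and 0.74), Calu, a calcium-binding protein of the secretory pathway (0.73 and 0.99, beside -0.09 and 0.01), Rtn4 (0.62 and 0.78) and Spin1 (0.62 and 0.83, beside -0.16).

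Among single integrin genes, Itgav had 0.69 ± 0.10 and Itga5 -0.48 ± 0.08, both past the threshold (beside 0.22 and -0.34 on their other tested probes), and Itgb1 had 0.66 ± 0.10 on the probe that passed and -0.61 ± 0.13 on the other tested probe (adjusted p = 0.0765). Probes of Hif1a (0.58 ± 0.09) and Nfe2l2 (0.64 ± 0.11) rose. The NRF2 target list was not higher as a whole, with 5 of its 20 tested genes lower and 1 higher at an unadjusted p under 0.05 (median -0.07). Cxcl12 rose on ILMN_2737302 (0.54 ± 0.10), beside 0.02 ± 0.10 and 0.49 ± 0.12 on its other tested probes. The largest differences of all belonged to probes without a gene name. ILMN_1215076 fell, with -3.16 ± 0.11 (8.95-fold lower), ILMN_3093150 rose by 2.59 ± 0.10 (6.02-fold), and ILMN_1219839 was at least 3.14-fold higher, being not above background on any CD133-negative array.

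The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 264 probes past the threshold and the highest of the other splits 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.

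Of the 264 probes, 81.8% were higher in CD133-positive cells, an excess that was weak at an unadjusted p under 0.05 (1564 of 2859 higher). It turned there with a median shift (825 of 3286), a setting that left the median of all tested probes at -0.13. It also turned there with probes of a gene averaged (719 of 1532) and with the brightest probe of each gene (646 of 1521). Past the adjusted threshold the excess held in both of these settings. There 77 were higher and 25 lower with probes averaged, and 82 and 24 with the brightest probe. A change of all transcripts is argued against for the 109 genes with another tested probe as a set, since the brightest such probe had a median of 0.034 against 0.68. The passing probes were picked from these data by smallest p, which raises their median. In the 76 of these genes whose other probe was the brighter, the medians were 0.014 and 0.69. A change of all transcripts stays open for the 26 of the 109 genes in which the other probe was also higher at an unadjusted p under 0.05. It also stays open for the 46 genes with 1 tested probe. The scaling stays open as part of the cause. The share of higher probes fell to 67.4% without background correction, the lowest of 5 other background and scaling settings. Both counts rose there, to 748 higher and 362 lower, so the fall in share cannot tell whether the scaling made the higher calls. A general gain of dim probes, from the length of the labelled RNA, unspliced RNA or array signal, stays open. Its size in the genes that passed is not known. In 3484 genes without a passing probe the dimmest probe lay a median of 0.026 (95% bootstrap interval 0.017 to 0.037) above the brightest. The median was 0.0093 where the 2 differed by under 1 log2 and 0.056 where these differed by over 3. A gain of this size, alike in all genes, is far below the smallest passing difference of 0.42. Genes with a passing probe were left out of this median, and the offset compresses dim probes. The median therefore cannot bound a gain that differs between genes, which was not tested. Use of other transcript ends or exons in CD133-positive cells may also give such a pattern and was not tested, as the probes' positions in the transcripts were not used here.

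Subclones of the line that differ in chromosome copy number could also separate with a surface marker. With the brightest tested probe of each gene, log2 differences of neighbouring genes correlated by 0.019 over 9417 genes. This small value still lay above most permutations (permutation p = 0.033). By camera 0 of 21 chromosomes, counting the mitochondrial one, passed (smallest adjusted p = 0.321, 2 at an unadjusted p under 0.05). Their mean log2 differences lay between -0.041 and 0.154, the highest for 7 mitochondrial genes. These values argue against large shifts of whole chromosomes, but cannot exclude changes of segments or of a small share of cells. Genomic gene length had a Spearman correlation of -0.0031 with the differences of these brightest probes across genes, which are not independent replicates. Length thus did not account for them. In 76 of the 109 genes with a higher probe and another tested probe, that other probe was brighter than the passing one. The correlation left those passing probes out and cannot tell whether length accounts for them. Regulation that differs between the populations stays open as a cause of the log2 differences and was not tested.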
